A study of Nicotiana tabacum with 6 samples.

How the data were processed

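Mature leaves of tobacco were profiled in 6 RNA-seq libraries, 3 from wild-type plants (WT) and 3 from plants overexpressing NtispH (OE-NtispH), with the group and the replicate number taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was captured on oligo(dT) beads, fragmented and copied with random hexamers, and the wording describes a strand-specific variant with dUTP in the second strand. Transcripts without a poly(A) tail, such as most chloroplast transcripts, are poorly captured by such a library.

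The authors deposited 1 table of FPKM values (fragments mapped to a transcript, divided by its length and by the library's mapped fragments), so the values were already scaled by transcript length and by library size. Per the submitters' processing notes, the tools were fastp, Bowtie2, HISAT2, StringTie and RSEM, with no versions or roles. The genome build, the annotation and the rule for fragments that map to several places are not given in the sources used here. Tobacco is an allotetraploid, so fragments from near-identical parental copies of a gene can be split between loci or assigned to either of them, and the level of any single copy, ISPH included, is uncertain to that extent. FPKM values sum to a fixed amount only roughly, and a change in the most abundant transcripts moves the values of all others.

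The table held 68476 loci, of which 61780 carried NCBI gene numbers and 6696 were assembled loci without one. Gene symbols came from a RefSeq gene table of the assembly ASM71507v2, used for names only and without coordinates: 49268 of the gene numbers matched and 12512 did not. Only 1081 of the loci, 895 of them tested, have a gene name beyond a locus number. Gene groups therefore cover only this named part of the genome.

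Values were analysed as log2(FPKM + 1), for the 40725 loci with a mean of at least 0.5 FPKM over the 6 libraries. The groups were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, robust, two-sided, Benjamini-Hochberg adjustment at 0.05), without a term for the replicate number. Fold changes are on the log2(FPKM + 1) scale. Standard errors are those of the moderated fit, and means ± SD are of FPKM. Gene lists were tested with camera (limma) against all other tested genes with a preset correlation of 0.01, and again with an estimated correlation and with fry, for lists with at least 5 tested genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

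The test, the groups, the alternatives and the rule for naming genes were set before the data were examined. The 35 gene lists set then relied on product names, which the tables used here do not hold. They were replaced by 42 lists of gene symbols, 37 of them with enough tested genes, written when only the mean of each gene over all 6 libraries had been seen and before any comparison of the groups. The rule for named genes took ISPH, the genes of the MEP pathway with a mean of at least 1 FPKM, the 12 largest rises and the 12 largest falls among genes past the threshold with at least 2 FPKM in the higher group and no overlap between groups, and the 3 genes of smallest p in each list that passed and in the lists of CYP71D genes and of diterpene synthesis and export, which stand in for lists of terpene synthases and trichome genes. A gene name was required in place of a product name, and 2 loci without a name were given in each direction. Only 10 named genes met the rule for falls. Genes shown for single libraries in the last part of the results were chosen after their values were seen.

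The number of reads per library is unknown. In FPKM, 1 fragment at a locus is worth an amount that falls with depth, so the commonest ratio of low values between libraries gives relative depth. Only ratios near 1 were searched, so a large difference in depth could not have shown. From 5600 to 6099 low loci per library, of which 10.8% to 12.7% stood at the commonest ratio, depth relative to WT replicate 1 was 1.12 and 1.18 in WT replicates 2 and 3 and 1.02, 1.03 and 1.06 in OE-NtispH replicates 1 to 3. No counting interval can be given without read counts.

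The fit was tested on simulated data with the real libraries' means and spread. In each of 5 draws 200 of 40725 genes were changed, all with a mean of at least 5 FPKM. Of genes changed by a log2 of 1, 52.0% were called, and of those changed by 2, 90.0%, while 3.4% of the calls were false. Changes in genes of lower level were not simulated. The list test found a shift of -0.5 in a list of 18 genes in 100% of 50 draws, with 7 false calls among the other lists. Real libraries share variation between genes that the simulated ones do not, so these shares describe a simpler case than the data.

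The alternatives were another pseudocount (0.1), no filter and a mean of at least 2 FPKM, median-of-ratios scaling, rescaling to TPM and quantile normalization, limma without trend or robust fitting, limma with library weights, the replicate number as a block, each library left out in turn, a log2 change of at least 1, an adjusted p under 0.01, and the other list tests. Leaving out 2 libraries together was added after the data were seen. No locus was left out except by the filter on low values, and no coordinates are given because the build is unknown.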

Results

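Poly(A) RNA from mature tobacco leaves (Nicotiana tabacum) was sequenced in 6 libraries, 3 labelled WT (wild type) and 3 labelled OE-NtispH (plants overexpressing NtispH). NtispH is the tobacco gene for the last enzyme of the plastidial MEP pathway, 4-hydroxy-3-methylbut-2-enyl diphosphate reductase, which makes the 5-carbon precursors of plastid terpenoids. The deposited table gave FPKM for 68476 loci, of which 15765 were at 0 in every library and 40725 had a mean of at least 0.5 FPKM and were tested. Between 48013 and 49085 loci were above 0 in a library, and the sum of FPKM per library lay between 747832 and 770304. The number of reads per library is not known from FPKM. The commonest ratio of low values between libraries put the depth of the other 5 libraries at 1.02 to 1.18 times that of WT replicate 1. This estimate searched only ratios near 1. The labels do not say whether the libraries of a group came from separate plants or transgenic lines, so the p-values measure only the spread between these libraries, which may be technical.

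The level of the overexpressed gene did not follow the group labels. ISPH (LOC107760258) was listed at 108.2 FPKM in the library labelled WT replicate 1, 3038 in WT replicate 2 and 558.6 in WT replicate 3. In the libraries labelled OE-NtispH it was at 2761, 684.6 and 853.7 FPKM in replicates 1, 2 and 3. The highest of the 6 values therefore stood in a library labelled WT. The group means were 1235 ± 1578 (SD, n = 3) in WT and 1433 ± 1153 (SD, n = 3) in OE-NtispH, a log2 change of 1.04 with a standard error of 1.37 (limma, adjusted p = 0.667), smaller than the spread between replicates. Without WT replicate 1 the log2 change was -0.15, and without WT replicate 2 it was 2.25 (limma, adjusted p = 0.345). Because the target does not check the labels, groups are named below by their labels, and every direction given is between the libraries labelled OE-NtispH and those labelled WT.

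Of the other genes of the MEP pathway, 1 of 2 abundant dxs loci passed the test, lower in the libraries labelled OE-NtispH. Transcripts of dxs (LOC107790348), for 1-deoxy-D-xylulose 5-phosphate synthase, the entry enzyme of the pathway, fell from 113.4 ± 0.16 FPKM (SD, n = 3) in WT to 70.9 ± 9.06 (SD, n = 3) in OE-NtispH, a log2 change of -0.68 ± 0.13 (SE; limma, adjusted p = 0.0473). Another dxs locus (LOC107818796) had 130.0 and 75.9 FPKM in WT and OE-NtispH and missed the threshold (limma, adjusted p = 0.0564). The low DXS locus LOC107773391 had 1.84 and 3.41 FPKM (limma, adjusted p = 0.305), the latter from 4.49, 4.36 and 1.38 in the 3 libraries. DXR (LOC107818871), the enzyme of the following step, had 26.9 ± 1.30 and 25.6 ± 2.78 FPKM (SD, n = 3), which differed by less than the spread between replicates. The list of 5 pathway genes, ISPH included, did not pass the list test (camera, adjusted p = 0.0776), and its median log2 change of -0.07 and its mean of 0.01 differed in sign.

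**Figure D1:**
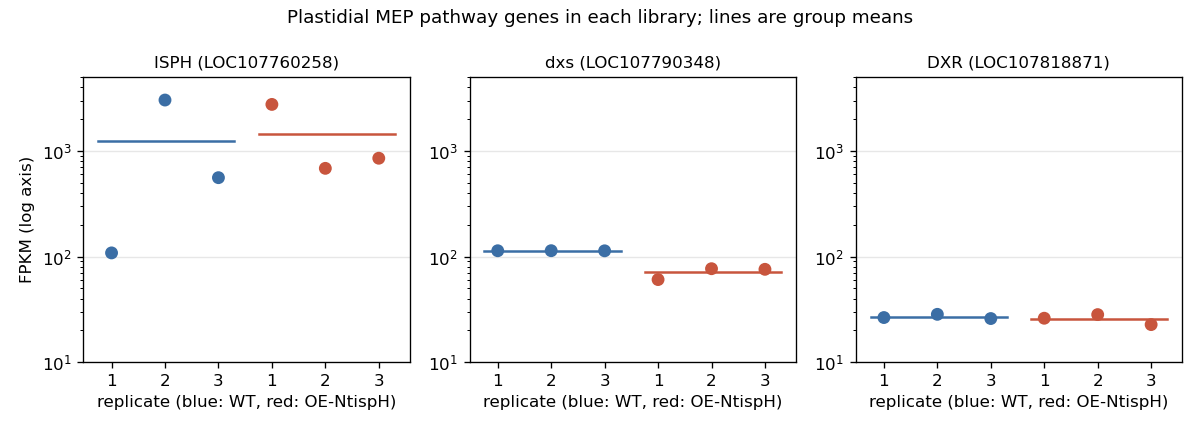
FPKM of ISPH, dxs and DXR in each library on a log axis, with WT in blue, OE-NtispH in red and lines at the group means. ISPH ranges from 108.2 to 3038 FPKM with its highest value in WT replicate 2, whereas dxs lies at 113.4 on average in WT and 70.9 in OE-NtispH, and DXR at 26.9 and 25.6.

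Between the groups as labelled, 737 genes passed the test, of which 506 were higher and 231 lower in OE-NtispH, and 38 of them carry a gene name. The proteinase inhibitor genes PI-Ia (LOC107787825) and PI-Ib (LOC107794480) encode a class of defence proteins against leaf-eating insects. Among the 38 named genes they had the largest rises on the log2(FPKM + 1) scale. By the ratio of mean FPKM, CYP72A52v1 (4.98) and NCAPP1 (3.91) rose more than PI-Ia (3.73) and PI-Ib (3.56). PI-Ia rose from 186.6 ± 66.5 to 695.4 ± 160.0 FPKM (SD, n = 3), a log2 change of 1.93 ± 0.28 (SE; limma, adjusted p = 0.0343), and PI-Ib from 174.3 to 619.9 FPKM. Lhcb6 (LOC107792047), a minor antenna protein of photosystem II, fell from 1797 ± 122.1 to 906.3 ± 236.4 FPKM (SD, n = 3), a log2 change of -1.02 ± 0.20 (SE; limma, adjusted p = 0.0486). GAPB (LOC107801158), a subunit of the Calvin cycle's glyceraldehyde 3-phosphate dehydrogenase, fell from 223.4 ± 19.6 to 106.1 ± 22.4 FPKM (SD, n = 3; limma, adjusted p = 0.0363).

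Chlorophyll synthesis genes went both ways. POR1 (LOC107820326), one of the genes for protochlorophyllide oxidoreductase, rose from 175.6 ± 45.3 to 464.6 ± 19.4 FPKM (SD, n = 3), while POR2 (LOC107795891), another gene for the same enzyme activity, fell from 285.3 ± 16.2 to 162.4 ± 32.8. The geranylgeranyl reductase gene chlP (LOC107783257), whose product makes the phytyl chain of chlorophyll and tocopherol, rose from 234.0 to 523.0 FPKM. The phytoene synthase gene psy-1 (LOC107772713), the entry enzyme of carotenoid synthesis, fell from 115.3 ± 10.8 to 61.6 ± 10.5 FPKM (SD, n = 3). All 4 passed the test (limma, adjusted p of 0.0295, 0.0497, 0.0406 and 0.0389 in the order given).

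Other named rises were those of gdh1 (LOC107778990), for glutamate dehydrogenase, from 10.7 to 26.8 FPKM, of a peroxidase (LOC107803841) from 190.6 to 469.0, of the glucosyltransferase NtGT4 (LOC107814959) from 18.4 to 47.2, and of 2 cytochrome P450 genes, CYP72A52v1 (LOC107825461) from 1.71 to 8.51 and CYP72A55 (LOC107822676) from 6.06 to 17.6. The remaining rises among the 12 largest were cig1 (LOC107777338), PROX1 (LOC107790219) and NCAPP1 (LOC107788423), with log2 changes of 1.40, 1.27 and 1.37. Only 10 named genes fell, and besides those above they were cas (LOC107800572), NtARP (LOC107773233), the subtilase gene SBT1.1B (LOC107789407), the plastid sigma factor gene sigA1 (LOC107795931) and DHS1 (LOC107796463), with log2 changes of -1.25, -1.10, -0.88, -0.82 and -0.73. Among loci without a name, the largest rises were those of LOC107790955, from 107.8 to 532.9 FPKM, and LOC107767796, from 0.894 to 9.49, and the largest falls those of LOC107811216, from 19.0 to 2.74, and LOC107812708, from 45.7 to 9.09.

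The calls came from limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment at 0.05, a scale that understates the change of low genes, and the smallest adjusted p was 0.0154. By a log2 change of 1 or more, 205 were higher and 101 lower. The groups did not overlap for 13249 of the tested genes, or 32.5%. Without a difference 10% would be the expectation, but genes vary together, so the share can lie far from it by chance. It was not counted for other splits of the libraries. The median log2 change of all tested genes was 0.13, so a change relative to that median is lower than the fitted one by this amount. With median-of-ratios scaling, which removes this shift, 135 genes were higher and 194 lower, and with quantile normalization 235 and 360, so the share of higher genes was 41% and 39.5% in place of 68.7%. Of the 737 genes, 308 and 460 passed under these 2 settings. With median-of-ratios scaling PROX1, chlP, Lhcb6, POR2, sigA1, EIL1 and nii2 missed the threshold (limma, adjusted p of 0.0504 to 0.0687), with log2 changes of 1.12, 1.04, -1.18, -0.98, -0.97, 0.60 and 0.74 in place of 1.27, 1.20, -1.02, -0.83, -0.82, 0.76 and 0.89 (SE of 0.12 to 0.23 in place of 0.14 to 0.23). With quantile normalization PROX1, chlP, Lhcb6, EIL1 and nii2 did (limma, adjusted p of 0.0516 to 0.0797), with log2 changes of 1.16, 1.10, -0.74, 0.65 and 0.73 (SE of 0.14 to 0.24). The count rests on single libraries: 0 genes passed limma without WT replicate 1 and 0 without OE-NtispH replicate 1 (10207 and 7221 at unadjusted p under 0.05), 1 without WT replicate 2, 17 without WT replicate 3, 1355 without OE-NtispH replicate 2 and 3103 without OE-NtispH replicate 3.

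Genes of the photosynthetic apparatus were lower in the libraries labelled OE-NtispH. All 18 nuclear-encoded photosystem and thylakoid genes tested had a log2 change below 0 (13 of 18 under quantile normalization), with a median of -0.42, or -0.55 relative to the median of all tested genes (camera, adjusted p = 5.1e-10; adjusted p = 0.46 with an estimated correlation). Lhcb6 alone passed the test for single genes. Lhcb4 (LOC107774251), another minor antenna protein, had 4688 ± 283.5 and 3215 ± 422.9 FPKM in WT and OE-NtispH (SD, n = 3; limma, adjusted p = 0.0789), and atpC (LOC107813955), a subunit of the chloroplast ATP synthase, had 421.9 and 290.1 (limma, adjusted p = 0.0617). With quantile normalization the list's median was -0.04, 5 of its 18 genes were above 0 and the call ended (camera, adjusted p = 0.0973). These genes are among the most abundant of the leaf, and the 100 most abundant loci held 30.6% to 32.2% of all FPKM in the WT libraries against 23.4% to 26.5% in the OE-NtispH libraries.

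The 5 genes of the Calvin cycle and carbonic anhydrase were below 0 in the same comparison, with a median log2 change of -1.09 (camera, adjusted p = 2.3e-05; adjusted p = 0.46 with an estimated correlation). Beside GAPB, the rubisco activase gene Rca (LOC107798594) had 1282 and 800.3 FPKM in WT and OE-NtispH and GAPA (LOC107780142) 1204 and 795.0, and neither passed alone (limma, adjusted p of 0.0549 and 0.0938). All 7 plastid ribosomal protein genes were below 0, with a median of -0.47 (camera, adjusted p = 2.9e-05; adjusted p = 0.464 with an estimated correlation), for example CL24 (LOC107762137) at 100.4 and 71.7 FPKM, CL4 (LOC107817573) at 105.0 and 70.2, and CL17 (LOC107821645) at 64.4 and 45.1. None of the 7 passed alone.

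Of 10 carotenoid synthesis genes 8 were below 0, with a median of -0.35 (camera, adjusted p = 4.8e-04; adjusted p = 0.46 with an estimated correlation). Next to psy-1, PSY2 (LOC107818367) was at 2.63 and 1.07 FPKM and the lycopene epsilon-cyclase gene LYCe (LOC107789691) at 37.4 and 27.6, without passing. The 15 tetrapyrrole and chlorophyll genes had a median of -0.14 with 11 below 0 (camera, adjusted p = 0.00285; adjusted p = 0.46 with an estimated correlation). This list ran lower although 2 of its 3 genes past the threshold, POR1 and chlP, rose. The cell wall list, with 8 of 10 genes below 0 and a median of -0.36, passed too (camera, adjusted p = 4.2e-04; adjusted p = 0.46 with an estimated correlation), led by the expansin genes Nt-EXPA1 (LOC107798333) at 16.1 and 8.23 FPKM and Nt-EXPA4 (LOC107808676) at 50.3 and 31.6, and the endoglucanase gene Cel8 (LOC107807143) at 3.08 and 1.56. Cell cycle genes had a median of -0.24 with 10 of 15 below 0 (camera, adjusted p = 0.00646; adjusted p = 0.46 with an estimated correlation). Loci of PCNA, the sliding clamp of DNA replication, stood at 5.47 and 3.06 FPKM (LOC107778290) and at 4.96 and 2.43 (LOC107779602), and the ribonucleotide reductase gene RNR1b (LOC107807190) at 3.08 and 0.959. No single gene of the cell wall and cell cycle lists passed.

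Genes of pathogenesis-related proteins and proteinase inhibitors were higher in the libraries labelled OE-NtispH. All 12 genes of this list were above 0, with a median log2 change of 0.99, or 0.86 relative to all tested genes (camera, adjusted p = 0.00126; adjusted p = 0.46 with an estimated correlation). PI-Ia and PI-Ib passed alone, and the osmotin-like gene PR-5dB (LOC107787812) had 244.3 ± 54.5 and 540.8 ± 163.5 FPKM (SD, n = 3; limma, adjusted p = 0.0571). In the list of ethylene synthesis and signalling 9 of 10 genes were above 0, with a median of 0.45 (camera, adjusted p = 0.00646; adjusted p = 0.46 with an estimated correlation). EIL1 (LOC107814269), a transcription factor of ethylene signalling, rose from 72.4 ± 7.43 to 122.9 ± 11.96 FPKM (SD, n = 3; limma, adjusted p = 0.0419), with EIL2 (LOC107810730) at 44.6 and 68.6 FPKM and EILP (LOC107759657) at 0.845 and 2.37.

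Nitrate and ammonium assimilation genes were above 0 in 9 of 10 cases, with a median of 0.56 (camera, adjusted p = 0.0323; adjusted p = 0.46 with an estimated correlation). Beside gdh1, the nitrite reductase gene nii2 (LOC107767028) rose from 12.97 ± 1.62 to 24.9 ± 3.72 FPKM (SD, n = 3; limma, adjusted p = 0.0363). The nitrate reductase gene NIA1 (LOC107823732) had 77.6 ± 8.27 and 329.5 ± 166.0 FPKM (SD, n = 3; limma, adjusted p = 0.0623). With median-of-ratios scaling 7 of the 10 were above 0, and without WT replicate 3 the list missed the threshold (camera, adjusted p = 0.0542). Of 9 genes of endoplasmic reticulum folding 8 were above 0, with a median of 0.52 (camera, adjusted p = 0.021; adjusted p = 0.644 with an estimated correlation), such as the chaperone genes BIP5 (LOC107771425) at 13.9 and 24.0 FPKM and BIP4 (LOC107818867) at 3.35 and 7.87, and the transcription factor gene NtbZIP60 (LOC107761889) at 13.5 and 20.1. Without OE-NtispH replicate 2 this list missed the threshold (camera, adjusted p = 0.113).

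The 3 remaining lists that passed in the direction of OE-NtispH had small shifts that depend on the scaling. Cytosolic ribosomal proteins had a median of 0.35 with 9 of 10 genes above 0, translation factors 0.35 with 13 of 14, and Rab, Ran and Rac GTPases 0.32 with 16 of 17 (11 of 17 with median-of-ratios scaling; camera, adjusted p of 0.0382, 0.021 and 0.0291; adjusted p of 0.631, 0.614 and 0.631 with an estimated correlation). Examples are RPS9 (LOC107832770) at 40.6 and 55.7 FPKM, eIF-4A-11 (LOC107785067) at 12.8 and 19.8, and the GTPase genes Rab5b (LOC107794083) at 4.64 and 6.87 and Rab8-3 (LOC107808111) at 32.9 and 47.2. No single gene of these lists passed, and with median-of-ratios scaling none of the 3 lists did (camera, adjusted p of 0.0951, 0.0509 and 0.11). In all, 14 of 37 lists tested passed camera with its preset correlation of 0.01. With an estimated correlation 0 passed, with 2 at unadjusted p under 0.05, and by fry 0 passed, with 17 at unadjusted p under 0.05 and a lowest adjusted p of 0.0533.

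**Figure D2:**
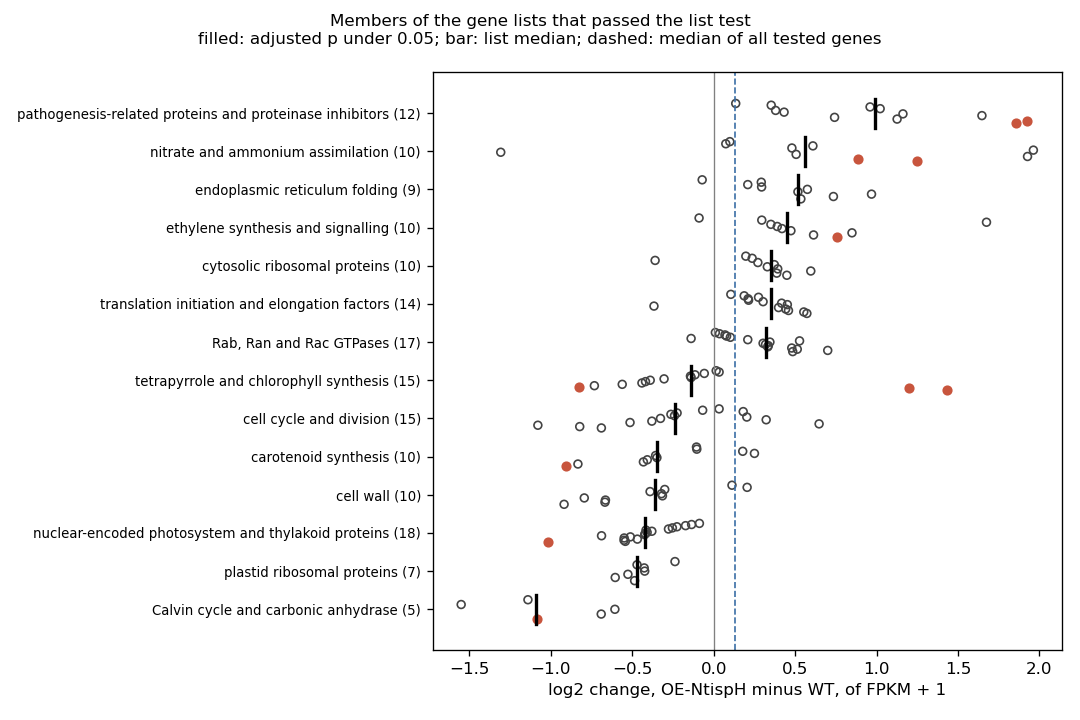
Log2 change of FPKM + 1 between OE-NtispH and WT (horizontal axis) for each tested member of the 14 lists that passed camera, with the number of tested genes in brackets; filled points passed limma at an adjusted p of 0.05, bars are list medians and the dashed line is the median of all tested genes, 0.13. The 18 photosystem genes lie below 0 and the 12 pathogenesis-related and proteinase inhibitor genes above 0. Under quantile normalization, which is not drawn, 5 of the 18 photosystem genes were above 0.

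The study's design asks about glandular trichomes, the leaf hairs that make the diterpenes and sugar esters of tobacco, and its title also names terpenoid metabolism. No gene in the list of diterpene synthesis and export passed the test, but only 3 of its genes were tested: NtABS, NtPDR1 and CYP71D20. NtABS (LOC107816701), for abienol synthase, was at 10.51 ± 1.12 and 10.7 ± 1.03 FPKM in WT and OE-NtispH (SD, n = 3; limma, adjusted p = 0.912), with a change that turned sign with the scaling, and the transporter gene NtPDR1 (LOC107799533) at 123.1 ± 19.5 and 180.8 ± 60.9 (SD, n = 3; limma, adjusted p = 0.272). CYP71D20 (LOC107759261), for the sesquiterpene hydroxylase of capsidiol synthesis, was at 39.3 ± 47.0 and 8.55 ± 6.41 FPKM (SD, n = 3; limma, adjusted p = 0.52), its WT values being 3.67, 21.6 and 92.5. The list of 6 CYP71D genes did not pass (camera, adjusted p = 0.568), with CYP71D47 (LOC107777210) at 15.9 and 22.9 FPKM, CYP71D48 (LOC107792854) at 4.72 and 7.50 and CYP71D5 (LOC107788281) at 0.401 and 0.913. Further terpenoid genes, named outside the rule, did not pass. All 4 prenyl diphosphate synthase genes were below 0, FPPS (LOC107795792) at 20.8 and 8.70 FPKM (limma, adjusted p = 0.0677). Of 5 mevalonate and sterol genes 3 were above 0 and 2 below, HMGR2 (LOC107777769) at 54.4 and 8.73 FPKM (SD of 47.6 and 2.33, limma, adjusted p = 0.126). Of 6 gibberellin metabolism genes 1 was below 0 and 5 above, GA2ox2 (LOC107829774) at 14.2 and 36.6 FPKM (limma, adjusted p = 0.0520). The RNA came from mature leaves and not from isolated trichomes, so a change confined to trichomes could be diluted. The depth and the 3 libraries per group also limit what these comparisons can show, and a difference that did not pass was not detectable here rather than absent.

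The libraries of each group stood together along the main axis of variation, with wide spread. The first principal component held 45.5% of the variance and separated the labels, with WT at -16.6, -41.6 and -64.2 and OE-NtispH at 60, 33.3 and 29. The second held 23.4% and ran across both groups, with WT replicate 1 and OE-NtispH replicate 3 at 42 and 37.6 and WT replicate 3 and OE-NtispH replicate 1 at -37.9 and -32.1. Pearson correlations across genes were 0.946 to 0.975 between WT libraries, 0.958 to 0.971 between OE-NtispH libraries and 0.919 to 0.966 between the groups, so that the ranges overlapped. WT replicate 2 had correlations of 0.975 and 0.968 with WT replicates 1 and 3 and of 0.938 to 0.955 with the OE-NtispH libraries. OE-NtispH replicate 3 had a higher correlation with WT replicate 1 (0.966) than with OE-NtispH replicates 1 (0.958) and 2 (0.959).

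**Figure D3:**
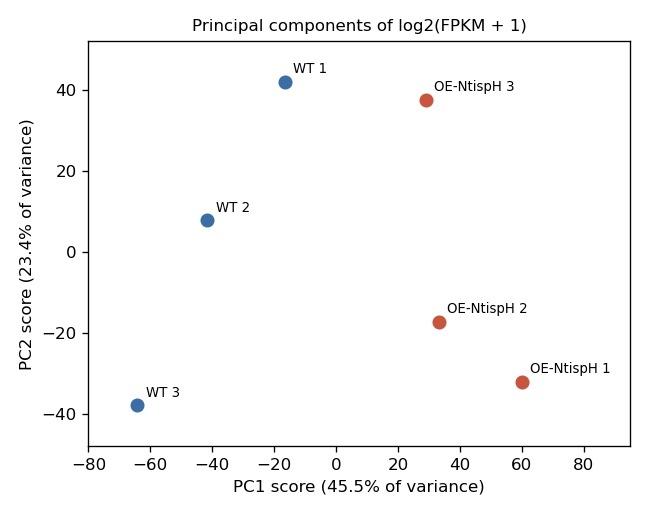
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) of the 40725 tested genes, which hold 45.5% and 23.4% of the variance, with WT in blue and OE-NtispH in red. The WT libraries lie below 0 and the OE-NtispH libraries above 0 on the first component, and both groups spread along the second.

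Inside the groups, single libraries differed in stress-related genes, which were chosen for display after their values were seen. ACRE1 (LOC107769990), a gene known for its rapid induction by a fungal elicitor, was at 0.376, 18.8 and 70.1 FPKM in WT replicates 1, 2 and 3 and at 11.4, 3.15 and 0.444 in OE-NtispH replicates 1, 2 and 3. The wound-responsive genes KED (LOC107827770) and WIZZ (LOC107798622) reached 56.8 and 57.1 FPKM in WT replicate 3, against 2.12 to 15.2 and 4.28 to 9.29 in the other libraries. The allene oxide cyclase gene aoc (LOC107768393), of jasmonate synthesis, was at 127.9 and 117.3 FPKM in OE-NtispH replicates 1 and 2, at 8.16 in OE-NtispH replicate 3 and at 15.7 to 22.1 in the WT libraries. NtPAL (LOC107792668), for the entry enzyme of phenylpropanoid synthesis, was at 131.4 and 66.2 FPKM in OE-NtispH replicates 1 and 2, 20.2 in replicate 3 and 17.4 to 24.0 in WT. The lists of elicitor-responsive genes, oxylipin and jasmonate genes, and phenylpropanoid genes did not pass between the groups (camera, adjusted p of 0.331, 0.096 and 0.331).

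**Figure D4:**
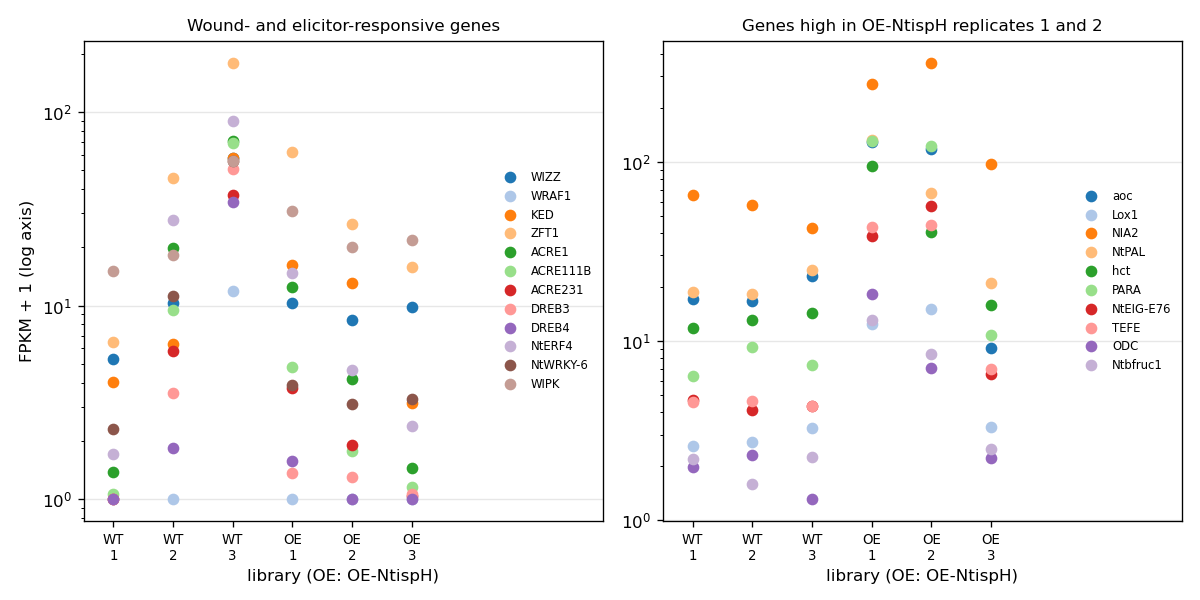
FPKM + 1 on a log axis of 12 wound- or elicitor-responsive genes (left) and 10 genes high in OE-NtispH replicates 1 and 2 (right) in each of the 6 libraries, 1 color per gene. On the left the values are highest in WT replicate 3 (ACRE1 at 70.1 FPKM), and on the right OE-NtispH replicate 3 lies near the WT libraries (aoc at 8.16 against 127.9 and 117.3 FPKM).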

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

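Of the settings here, only the fits without 2 libraries together were chosen after the data were seen. The number of genes past the threshold, 737, did not hold: it was 684 with a pseudocount of 0.1, 817 after rescaling to TPM and 595 after quantile normalization, against 38 with no filter on low values, 1375 with a mean of at least 2 FPKM, 329 with median-of-ratios scaling, 53 by limma without trend or robust fitting, 2813 with library weights, 306 by a log2 change of 1 or more and 0 at an adjusted p under 0.01 (limma, 10747 at unadjusted p under 0.05). Leaving out 1 library gave 0 to 3103 genes. Those at 0 were the fits without WT replicate 1 and without OE-NtispH replicate 1 (10207 and 7221 at unadjusted p under 0.05). The cause was not tested, beyond the fewer libraries in each such fit. Without WT replicates 2 and 3 together 1 gene passed, the lone WT library being assumed to vary like the others, and without WT replicate 2 and OE-NtispH replicate 3 together 737 passed (579 higher and 158 lower), 221 of them shared with the 737 of the full set.

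ISPH stayed short of the threshold in each setting. Its log2 change was -0.151 to 2.248 when 1 library was left out, the reversal being without WT replicate 1, 3.43 without WT replicates 2 and 3 together, and 2.48 without WT replicate 2 and OE-NtispH replicate 3 together. The other reversals are those of 2 genes that passed in no setting named here: DXR (LOC107818871), at -0.139 to 0.012 with 1 library left out and above 0 without OE-NtispH replicate 3, and NtABS (LOC107816701), at -0.119 with median-of-ratios scaling, -0.128 with quantile normalization and -0.056 to 0.08 with 1 library left out, below 0 without WT replicate 3 and without OE-NtispH replicate 2.

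The number of lists past the threshold was 14, and 10 to 19 with 1 library left out, 9 with a mean of at least 2 FPKM, 0 with an estimated correlation and 0 by fry (2 and 17 at unadjusted p under 0.05). The lists of carotenoid synthesis, tetrapyrroles, the Calvin cycle, plastid ribosomes, the cell wall, the cell cycle, ethylene and pathogenesis-related proteins passed camera with its preset correlation in each setting with all libraries or with 1 left out, and the photosystem list in each but quantile normalization.

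The replicate numbers do not pair the libraries: the correlations of same-numbered deviations were -0.13, 0.04 and -0.16. For WT replicates 1, 2 and 3 the OE-NtispH library with the highest such correlation was replicate 3, 2 and 1. No block by that match, which was found in these same data, was fitted. With the replicate number as a block 68 genes passed, 48 higher and 20 lower, 55 of them among the 737, ISPH had a log2 change of 1.04 and 14 lists passed. Depth limits low genes most, since 1 fragment is a large part of their value.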

Other observations

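The tests here were chosen after their results had been seen, except that for a shared copy of ISPH and that for scaling of the photosystem list. The 10 splits of 3 libraries against 3 are too few for a share under 0.05: the real split called 737 genes, the highest other split 4, and 1 split, the real one, gave as many.

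In OE-NtispH replicates 1 and 2, 131 loci were at 3 FPKM or more and at least 2.5 times above every other library (with 0.3 FPKM added to the latter), against at most 13 in any other of the 15 pairs. Among them were aoc (LOC107768393), the lipoxygenase gene Lox1 (LOC107806322) at 11.4 and 14.0 FPKM against 2.29 in OE-NtispH replicate 3 and 1.58 to 2.25 in WT, the auxin-regulated gene PARA (LOC107772524) at 129.6 and 121.8 against 9.74 and 5.39 to 8.22, and the nitrate reductase gene NIA2 (LOC107785409) at 270.2 and 355.0 against 96.2 and 41.6 to 64.2. The phenylpropanoid genes NtPAL (LOC107792668) and hct (LOC107796658), the latter at 93.7 and 39.4 FPKM against 14.8 and 10.8 to 13.2, and the ornithine decarboxylase gene ODC (LOC107815922), at 17.3 and 6.10 against 1.22 and 0.309 to 1.30, had the same profile. The genes named here were picked for this profile and are counted in the lists below that hold them. In 3 of the lists they belong to, 6 of 7 oxylipin and jasmonate genes, 13 of 22 phenylpropanoid genes and 5 of 10 nitrate and ammonium genes were higher in both of these libraries than in each of the other 4, against at most 1, 4 and 3 for any other pair of libraries, which was counted after the profile had been seen.

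A further 362 loci were high in WT replicate 3 alone by the same measure, against at most 33 in any other single library. They include the DREB transcription factor genes DREB3 (LOC107807923) and DREB4 (LOC107776941), at 49.5 and 33.2 FPKM there and at most 2.53 and 0.845 elsewhere, and WRAF1 (LOC107773005), at 10.9 FPKM and listed at 0 in the other 5 libraries. The ethylene response factor gene NtERF4 (LOC107790518) was at 88.4 FPKM in WT replicate 3, 26.7 in WT replicate 2, 0.713 in WT replicate 1 and 1.39 to 13.7 in the OE-NtispH libraries.

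ISPH does not follow the labels. Exchanging the libraries labelled WT replicate 2 and OE-NtispH replicate 3 left 0 genes past the threshold (limma, 1440 at unadjusted p under 0.05) in place of 737. A count of 0 is not particular to this exchange, as the highest count of any split but the labelled one was 4. It argues against a swap of this pair only if overexpression drives the strongest split, which ISPH does not bear out. The same limit holds for the positions on the first principal component given below. Among loci running opposite to ISPH (r of -0.9 or less) the largest range was 34.0 FPKM, against 2930 FPKM for ISPH. A copy gaining the reads that ISPH loses need not reach that r, because the relation is curved on the log2 scale. The screen therefore decides neither on such a copy nor on a copy that shares reads and rises with ISPH. Depth is divided out in FPKM. Its estimated 1.18-fold range cannot be set against the 28.1-fold range of ISPH, because the estimate searched only ratios near 1. A wrong label on WT replicate 2 is argued against by its position of 0.12 on the first principal component of the other 5 libraries, where 0 is the WT mean and 1 the OE-NtispH mean, as held-out positions kept the labels apart there (WT 0.12 to 0.46, OE-NtispH 0.63 to 0.96; SD within groups of 0.18), although on 200 genes chosen to separate the labels, where it stood at 0.14, OE-NtispH replicate 3 at 0.22 lay below WT replicate 1 at 0.31. A wrong label on OE-NtispH replicate 3 is not decided by its position of 0.63, within that SD of the midpoint, as was WT replicate 1 at 0.46. Its highest correlation was with WT replicate 1 (0.966). Such a wrong label alone would not account for ISPH, as the highest value, 3038 FPKM, would still stand in WT replicate 2. Without OE-NtispH replicate 3 the log2 change of ISPH was 1.27 (limma, adjusted p = 0.716). Open and untested is a difference in the gene's own expression between plants or lines of a group. So is transcript carried over from a strongly expressing sample. Reads shared with a copy that falls or rises as ISPH rises stay open too.

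The elicitor genes were higher as a set in WT replicate 3 than in WT replicate 1. The 15 ACRE and EIG genes had a median ratio of 1.95 on FPKM + 1, 13 of them above 1. Depth, divided out in FPKM, would leave a ratio near 1. The set includes genes displayed above for this profile, and the ratio of all genes was not taken. In WT replicate 2 the median ratio to WT replicate 1 was 1.16, with 10 of 15 above 1. List medians of log2(FPKM + 1) in WT replicates 1, 2 and 3 were 1.84, 2.54 and 3.51 for the ACRE and EIG genes. They were 2.4, 3.36 and 5.49 for WRKY transcription factor genes, and 2.34, 3.84 and 4.97 for ERF and DREB genes. WT replicate 2 therefore lay between WT replicates 1 and 3 in each list. In the OE-NtispH libraries the medians were 1.93 to 2.33, 3.07 to 3.36 and 2.43 to 4.14, in the same order. A candidate explanation of the high values in WT replicate 3 is a short stimulus, such as handling, before the leaf was frozen. In that case fast genes would be up without a rise of the slow proteinase inhibitors. The mean ratio of PI-Ia and PI-Ib, WT replicate 3 over WT replicate 1, was 0.51. They were not raised, which would also hold without a stimulus. WT replicate 1 had their highest WT values (258.4 and 245.8 FPKM), which a stimulus in WT replicate 3 does not predict. The comparison rests on 2 genes and 1 library and does not decide. A difference in growth or time of day, not recorded in the labels, stays open beside the stimulus.

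The photosystem genes of the libraries labelled OE-NtispH may be lower as part of a wider pattern. A stimulus in WT replicate 3 alone does not account for it, since without that library the list's medians per library differed by -0.42 (95% interval of -0.78 to -0.07), and neither does 1 scaling factor per library, since the list's median was -0.58 after median-of-ratios scaling. A stimulus in both WT replicates 2 and 3 stays open, as the value of -0.38 against WT replicate 1 rests on 1 library. However, the other 185 loci among the 200 most abundant had a median log2 change of -0.37, with 139 below 0, and quantile normalization, which equalizes that end of the distribution, moved the list to -0.04. Because only 14 of those 185 loci carry a name, a change of photosystem genes and a lower level of the most abundant loci of any kind cannot be told apart here, and overexpression stays untested as a cause, as ISPH does not follow the labels.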
